A study of Mus musculus with 16 samples.

How the data were processed

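The deposited values were gene-level tables for 16 libraries of mouse cortical neurons, 4 in each of 4 groups set by α-synuclein fibrils (loaded or untreated) and by microglia (present or absent). Libraries were made with the QuantSeq forward kit, which primes at the poly(A) tail, so counts come from 3′ ends and do not scale with gene length, per the labels' protocols. Reads were aligned with STAR to the mouse assembly mm10 and handled in Partek, with DESeq2, per the submitters' processing notes, which give no versions. The counting tool, its strand setting, the annotation and any use of molecular identifiers were not given in the sources used here. The authors deposited raw counts per gene symbol without normalization, with 16934 genes; 14 very large counts, all of Rn45s, carry 6 significant digits. The second deposited table holds a score per gene, the authors' normalized values rounded to whole numbers; 99.99% of its entries lay within 0.6 of the raw count times a constant per library. Reads from PCR copies are not independent molecules, so counting error understates the true error.

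Total counts were 6511516 to 13986374 per library. Between 41 and 666 genes per library had a count of 0 where the mean of the other libraries was at least 100, and chi-square per degree of freedom between libraries of a group was 71.2 to 276, so no pair was alike within sampling noise, as 2 runs of one library would be. This does not show separate cultures, since libraries made apart from one culture would differ as well, and each library was counted once as the labels list it. Groups were taken from the treatment label of each sample. Replicate numbers name the 4 runs of neighbouring library codes in the titles, each run holding a library of every group. The labels do not say that libraries sharing a number came from one culture or animal.

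Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 13139, scaled by TMM, and fitted in one robust quasi-likelihood model with a mean per group over all 16 libraries. Contrasts were fibrils in neurons alone, microglia without fibrils, microglia with fibrils, fibrils in co-culture, and their interaction. An average of the microglia effects and one of the fibril effects were added after the separate contrasts had been seen. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, and CPM and log2 CPM (prior count 2) used the TMM scaling, with summed CPM of cell type lists taken over all genes before the filter. Gene lists, 33 in all, were fixed before the data were examined; 31 had at least 5 tested genes, while the vascular and fibroblast list had 4 and the list of genes encoded by the mitochondrial genome 0. They were tested with camera on voom values (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists. Levels of 7 cell type lists were compared with exact two-sided permutation tests, where 4 against 4 cannot go below p = 0.0286. Python 3.11.15 with pandas 2.3.3 joined the tables, and matplotlib 3.10.9 drew the plots. Of the gene symbols, 96.2% matched a single gene of the GENCODE annotation used for positions.

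Genes named were chosen by a rule fixed before the data were examined. In each contrast these were up to 10 with the largest rise and 10 with the largest fall among called genes with a mean log2 CPM above 2 and no overlap between groups (5 and 5 for the interaction), with predicted gene models skipped. With fewer than 5 called genes, the 5 with the smallest p were named as not passing. Up to 4 called members of each list that camera called or that held at least 3 called genes, and the most abundant 5 genes of cell type lists, were added. Of the genes this rule covers, 1 is not reported here. The rule was also applied to the averaged contrasts. Beyond the rule, members of lists called in the fibril contrasts were named after their values were seen, and the text says so. Gad1 and Gad2, and members of uncalled lists named in the closing section, were chosen likewise.

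The edgeR, limma-voom and DESeq2 tests were tested on simulated data drawn from these libraries, 13139 genes with 200 changed in 5 simulations. For microglia without fibrils, edgeR recovered 0.84% of genes changed 2-fold, 16.2% at 4-fold, 28.6% at 8-fold and 48.1% at 16-fold; for the averaged microglia contrast 3.38%, 26.6%, 45.1% and 60.0%. False calls made up 3.9% and 3.37% of edgeR's calls, 5.2% and 3.62% of limma-voom's, and 51.5% and 53.8% of DESeq2's (version 1.42.0). Lists changed 2-fold were recovered in 10 of 10 cases by each list test. Of 145 unchanged lists camera called 1 at the preset correlation for microglia without fibrils and 0 for the average. Each simulated gene was drawn on its own, so this does not test list calls under the correlation between genes of real libraries. Among other splits of the real libraries for microglia without fibrils, camera called up to 17 of 31 lists.

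Alternatives were DESeq2, limma-voom, limma on the authors' normalized values, DESeq2 size factors or library totals as scaling, no filter and a stricter filter (30 counts in 4 libraries), the groups of a contrast alone, a replicate block, an adjusted p under 0.01, a fold of 1.2, a microglial covariate, microglial and co-culture genes left out (768), and each library left out in turn. Added after seeing the data were leaving out Rn45s and leaving out the 2 libraries rich in microglial transcripts. Leaving out genes of the mitochondrial genome was not run, since the table held 0 of them. Comparisons that share libraries were set beside simulated unchanged groups. The explanations weighed in the closing section, and every count of other splits of the libraries, were written down as tests after the results they bear on had been seen.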

Results

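Messenger RNA was measured in primary cortical neurons of C57BL/6 mouse embryos, grown for 14 days, with a kit that reads the 3′ ends of transcripts. Fluorescent fibrils of α-synuclein, the neuronal protein that aggregates in Parkinson's disease, had been given to some neurons at 0.1 µM over 16 h, and the others were untreated. Each kind was then kept alone or cultured for 6 h with microglia, the resident immune cells of the brain. The 16 libraries formed 4 groups of 4: untreated neurons alone, loaded neurons alone, untreated neurons with microglia, and loaded neurons with microglia. The series asks how microglia act on neurons that carry fibrils, and its title names tunnelling nanotubes, thin membrane channels between cells. The labels do not say how neurons were parted from microglia before RNA was isolated. Nor do they say that the libraries came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. Total counts ranged from 6511516 to 13986374 per library, of which Rn45s, a ribosomal RNA precursor, took 9.35% to 26.8%. Between 10817 and 13079 genes were detected per library. Libraries of one group differed widely: the correlation of log2 CPM between them was 0.652 to 0.798, and the biological coefficient of variation was 1.17.

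Transcripts of the oligodendrocyte lineage, the glia that make myelin, were more abundant in each of the 8 co-culture libraries than in any of the 8 libraries of neurons alone. Their summed level was 1552 ± 473 CPM in untreated neurons alone and 5682 ± 1854 CPM with microglia (SD, n = 4 each). In loaded neurons it was 2474 ± 699 CPM alone and 8036 ± 1755 CPM with microglia (SD, n = 4 each). The most abundant members were Olig1 and Olig2, transcription factors of the lineage, Gpr17, a receptor of its differentiating precursors, and Bcas1 and Cnp, which mark forming oligodendrocytes. The mean log2 level of the list was higher with microglia by 1.75 without fibrils and by 1.76 with fibrils. The exact permutation test gave p = 0.0286 for both (two-sided), the smallest value that 4 libraries against 4 allow. The adjusted p over the 21 comparisons of cell type levels was 0.15, which does not pass. With that floor, an adjusted p could pass only if many of the 21 comparisons lay at the floor, so this outcome decides little.

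Microglial identity genes were abundant in 2 libraries, replicate 1 of each co-culture group. Their summed level there was 1215 CPM without fibrils and 1654 CPM with fibrils, against 30.3 to 105 CPM in the other 6 co-culture libraries and 9.60 to 61.1 CPM in neurons alone. The mean log2 level of the list differed by 2.04 without fibrils and 2.13 with fibrils between co-culture and neurons alone (exact permutation p = 0.2 and 0.343), and by 0.88 between loaded and untreated co-cultures (exact permutation p = 0.629). Without replicate 1 of the co-culture group the first 2 differences were 0.50 and 0.65, and without replicate 1 of the loaded co-cultures the last was -0.60. Csf1r, C1qa, Ctss, C1qc and Laptm5 were the most abundant of these genes. The mean log2 level of neuronal identity genes was 5.41 and 5.55 in these 2 libraries and 5.45 to 7.51 in the other 6 co-culture libraries. Excitatory-neuron transcripts summed to 10345 ± 2345 CPM in untreated neurons alone and 2629 ± 1597 CPM with microglia, and to 5782 ± 3641 and 1786 ± 625 CPM in loaded neurons (SD, n = 4 each). Their mean log2 level was lower with microglia by values of -2.22 without fibrils (exact permutation p = 0.0286) and -1.69 with fibrils (exact permutation p = 0.143), both with an adjusted p above the threshold (0.15 and 0.375). The inhibitory-neuron level differed by -0.16 and -0.63 (exact permutation p = 0.714 and 0.514). For astrocytes the differences were -0.42 and -1.59 (exact permutation p = 0.543 and 0.0857). Genes of vessels and fibroblasts summed to 10.8 to 34.7 CPM as group means.

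**Figure D1:**
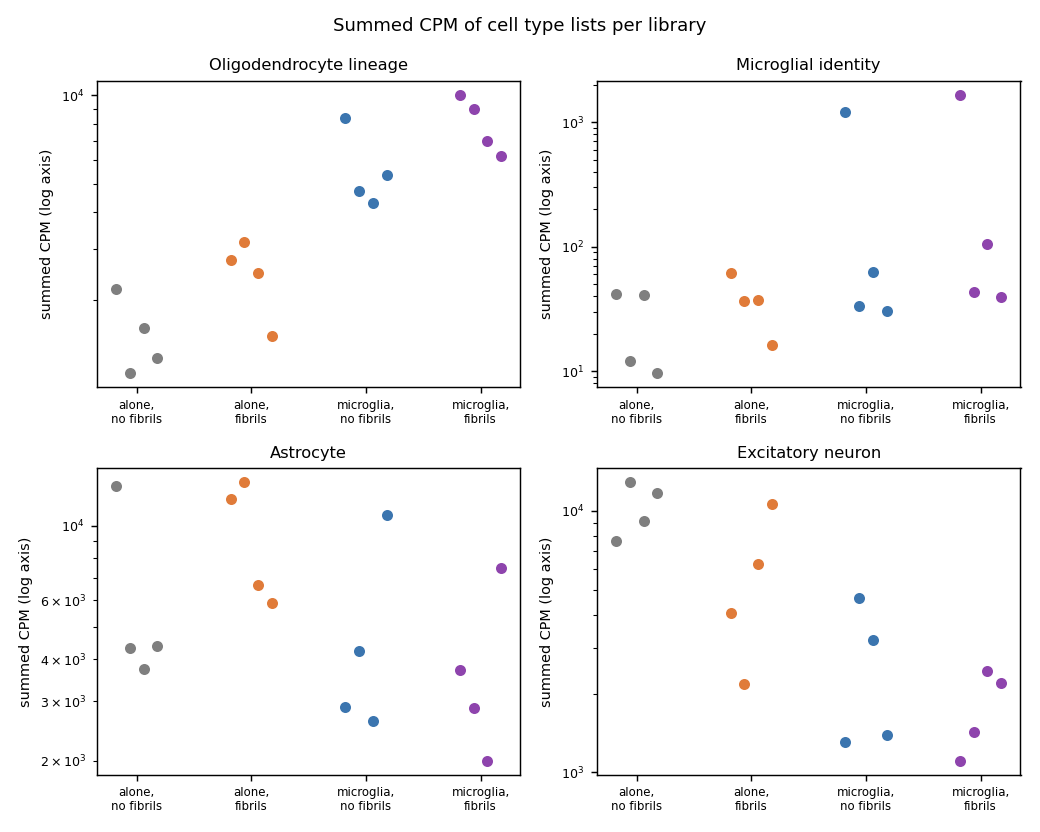
Summed CPM (log axis) of 4 fixed cell type lists in each of the 16 libraries, by group; each point is a library. Oligodendrocyte-lineage sums lie between 1130 and 3156 CPM in neurons alone and between 4287 and 10009 CPM with microglia, and the microglial sum is 1215 and 1654 CPM in 2 libraries.

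In libraries of untreated neurons, Pdgfra, Lhfpl3 and Olig1 of the oligodendrocyte lineage were higher, and Thy1 and Camk2n1 lower, with microglia than alone. Such a difference can come from the mix of cells in a library or from a change within neurons, as the closing section weighs. Pdgfra, the growth factor receptor of oligodendrocyte precursors, rose from 86.7 ± 24.3 to 441 ± 76.4 CPM (SD, n = 4 each), a log2 change of 2.34 ± 0.40 (SE; adjusted p = 0.0217). Lhfpl3 rose by 2.66 ± 0.51, Olig1 by 1.83 ± 0.37, Sox8, a transcription factor of glia, by 2.64 ± 0.52, and Cacng4, an AMPA receptor auxiliary subunit, by 1.89 ± 0.35 (adjusted p 0.033 to 0.0407). Lmnb1, a nuclear lamina protein, and Aspm, a protein of the mitotic spindle pole, rose by 2.27 ± 0.45 and 2.31 ± 0.45 (adjusted p = 0.0407 for both). Sh3bp4 and Abtb2 rose by 2.82 ± 0.51 and 2.63 ± 0.42 (adjusted p = 0.033 and 0.0217). Thy1, a surface protein of mature neurons, fell from 301 ± 51.9 to 54.6 ± 21.3 CPM (SD, n = 4 each; log2 change -2.46 ± 0.41, adjusted p = 0.0217). Camk2n1, an inhibitor of the kinase CaMKII, had a change of -2.04 ± 0.36, and Slc25a12, a mitochondrial aspartate and glutamate carrier, of -2.23 ± 0.43 (adjusted p = 0.0256 and 0.0407). Actr3b, Mapk8ip1, Ywhag and Atp6v0c, a subunit of the vacuolar proton pump, fell as well, with changes between -1.45 and -2.22 (adjusted p 0.0407 to 0.0438).

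By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 16 of 13139 genes changed, 9 up and 7 down, and 1196 had an unadjusted p under 0.05 against 657 expected by chance. DESeq2 called 295 genes, limma-voom 92 and limma on the authors' normalized values 35, and edgeR called 26 with no filter, 5 against a fold of 1.2 and 1 from the libraries of the 2 groups alone. A replicate block raised the edgeR count, as the closing section gives. With library totals as the scaling the split was 45 up and 5 down, and the median log2 change of all genes moved from -0.02 to 0.19. The count depended on single libraries. It was 39 without replicate 1 of the untreated neurons alone, 0 without their replicate 2 or 3, and 1 without their replicate 4. It was 0 without replicate 1 of the untreated co-cultures, the library rich in microglial transcripts, 7 without their replicate 2 and 2 without their replicate 4.

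Of the 16 tested oligodendrocyte-lineage genes, 15 were higher and 3 passed the test over all genes, 13 when adjusted over the list alone. This list rose by camera (median log2 change 1.79, adjusted p = 1.41e-14) and held with an estimated correlation between genes (adjusted p = 0.0091). Cell cycle genes rose as a list, with all 21 higher (median 1.76, adjusted p = 2.19e-13), as did ribosomal protein genes (median 0.41, adjusted p = 1.46e-08). Their adjusted p values were 0.191 and 0.317 with an estimated correlation. Presynaptic genes (25 of 26 lower, median -1.87), neuronal identity genes (20 of 22 lower, median -1.81), excitatory-neuron genes (17 of 19, median -1.55), immediate early genes of neuronal activity (25 of 25, median -1.46) and postsynaptic genes (16 of 22, median -1.38) fell by camera (adjusted p from 1.05e-16 to 2.93e-06). With an estimated correlation their adjusted p was 0.191 to 0.317. Glycolysis and hypoxia genes fell with a median of -0.95 (adjusted p = 2.16e-05, and adjusted p = 0.191 with an estimated correlation). Nuclear genes of oxidative phosphorylation, the integrated stress response and Parkinson's disease genes fell with medians of -0.28, -0.39 and -0.48 (adjusted p 0.003, 0.0127 and 0.0292), and the oxidative phosphorylation and Parkinson's disease calls were lost with library totals as the scaling (adjusted p = 0.193 and 0.0708). These lists had adjusted p values of 0.569, 0.505 and 0.191 with an estimated correlation. Interferon response and microglial identity genes rose by camera (adjusted p = 0.000742 and 0.0127; with an estimated correlation, adjusted p = 0.408 and 0.569). Without the 2 libraries rich in microglial transcripts the microglial list had an adjusted p of 0.457. By fry, the oligodendrocyte-lineage list passed (adjusted p = 0.000637). Cell cycle, neuronal identity, excitatory-neuron, postsynaptic, glycolysis and hypoxia, and Parkinson's disease genes passed as well (fry adjusted p 0.0337 to 0.0475). The other lists called by camera did not.

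In libraries of loaded neurons, Pdgfra and Lhfpl3 were again higher, and Thy1 and Camk2n1 lower, with microglia than alone. Pdgfra rose from 37.2 ± 16.2 to 297 ± 163 CPM (SD, n = 4 each), a log2 change of 2.99 ± 0.41 (SE; adjusted p = 0.00237), and Lhfpl3 rose by 2.94 ± 0.52 (adjusted p = 0.0229). Enpp6, a phosphodiesterase of newly forming oligodendrocytes, rose by 2.17 ± 0.44 (adjusted p = 0.0487), and Cacng4 by 1.75 ± 0.34 (adjusted p = 0.0388). Marcks, a substrate of protein kinase C at the membrane, rose by 1.80 ± 0.32, Cilk1, a kinase of the cilium, by 2.25 ± 0.36, and Zfp462, Srek1 and Sulf2 by 1.69 to 2.17 (adjusted p 0.0149 to 0.0388). Thy1 fell from 170 ± 82.5 to 32.0 ± 13.5 CPM (SD, n = 4 each; log2 change -2.40 ± 0.41, adjusted p = 0.0209). Gpi1, an enzyme of glycolysis, and Pdhb, a subunit of pyruvate dehydrogenase, fell, with changes of -2.17 ± 0.38 and -1.80 ± 0.33 (adjusted p = 0.0209 and 0.0292). Sqstm1, the autophagy receptor p62, fell from 484 ± 56.0 to 154 ± 48.8 CPM (SD, n = 4 each; -1.65 ± 0.33, adjusted p = 0.0399). Cd151, a tetraspanin, and Camk2n1 had changes of -2.40 ± 0.47 and -2.02 ± 0.36 (adjusted p = 0.0388 and 0.0209).

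The edgeR test called 15 of 13139 genes, 9 up and 6 down, and 1540 had an unadjusted p under 0.05 against 657 by chance. DESeq2 called 492 genes, limma-voom 40 and limma on the authors' normalized values 18, and edgeR called 26 with no filter, 9 against a fold of 1.2 and 0 from the libraries of the 2 groups alone. A replicate block raised this edgeR count too, as the closing section gives. With library totals the split was 26 up and 5 down. Among loaded neurons alone, leaving out replicate 1, 2, 3 or 4 gave 9, 9, 7 and 26 genes. Among loaded co-cultures, leaving out replicate 1, the library rich in microglial transcripts, gave 4 genes, and leaving out replicate 2 or 3 gave 1 and 2. The count of called lists moved from 13 to 6 without replicate 4 of the loaded neurons alone.

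All 16 tested oligodendrocyte-lineage genes were higher, of which 3 passed over all genes and 13 when adjusted over the list alone. The list rose (median 1.74, camera adjusted p = 6.47e-17) and held with an estimated correlation (adjusted p = 0.0047). Cell cycle genes rose again, with all 21 higher (median 1.2, adjusted p = 1.79e-08, and adjusted p = 0.215 with an estimated correlation). Nuclear oxidative phosphorylation genes fell, with 72 of 75 lower (median -0.71, adjusted p = 9.19e-21), as did glycolysis and hypoxia genes, with 21 of 23 lower (median -1.18, adjusted p = 1.01e-09). Both had an adjusted p of 0.0709 with an estimated correlation. Antioxidant genes of the Nrf2 pathway fell in 27 of 27 members (median -1.19, adjusted p = 1.75e-13) and astrocyte genes in 16 of 18 (median -1.37, adjusted p = 1.18e-09). With an estimated correlation the adjusted p values were 0.156 and 0.215. Without fibrils these 2 lists were not called (medians -0.21 and -0.30, camera adjusted p = 0.601 and 0.189). The loaded neurons alone, the reference here, also enter the fibril contrast in which both lists were higher. These falls therefore do not show a reversal by microglia. Presynaptic, excitatory-neuron, neuronal identity and postsynaptic genes fell with medians of -1.40, -1.63, -1.15 and -0.84 (adjusted p from 8.17e-05 to 0.0406). Their adjusted p was 0.609 to 0.679 with an estimated correlation. Integrated stress response and autophagy genes fell with medians of -0.75 and -0.27 (adjusted p = 0.00812 and 0.0324), and microglial identity genes rose (adjusted p = 0.0215). With an estimated correlation these had adjusted p values of 0.596, 0.215 and 0.668. The autophagy, microglial and postsynaptic calls were lost with library totals (adjusted p = 0.0928, 0.0542 and 0.0741). By fry, the oligodendrocyte-lineage, oxidative phosphorylation, glycolysis and hypoxia, and autophagy lists passed (adjusted p 0.000503 to 0.0298), and the other called lists did not.

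The 2 microglia comparisons share no library, and 5 genes were called in both, Cacng4, Lhfpl3 and Pdgfra up and Camk2n1 and Thy1 down. Independent lists of these sizes would share 0.00936. Both comparisons came from one fit with a shared variance estimate per gene, so the lists are not independent and this value is no strict reference. Fitted on the groups of each contrast alone, fewer genes were called, as given above. All 16 genes called without fibrils had the same direction with fibrils, each with an unadjusted p under 0.05. All 15 genes called with fibrils had the same direction without them, 14 with an unadjusted p under 0.05. Across 13139 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.264 and a Spearman correlation of 0.376. Unchanged simulated groups gave -0.00152 ± 0.0154 (SD, 10 simulations). Each gene was drawn on its own there, so that SD leaves out variation that genes of real libraries share.

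**Figure D2:**
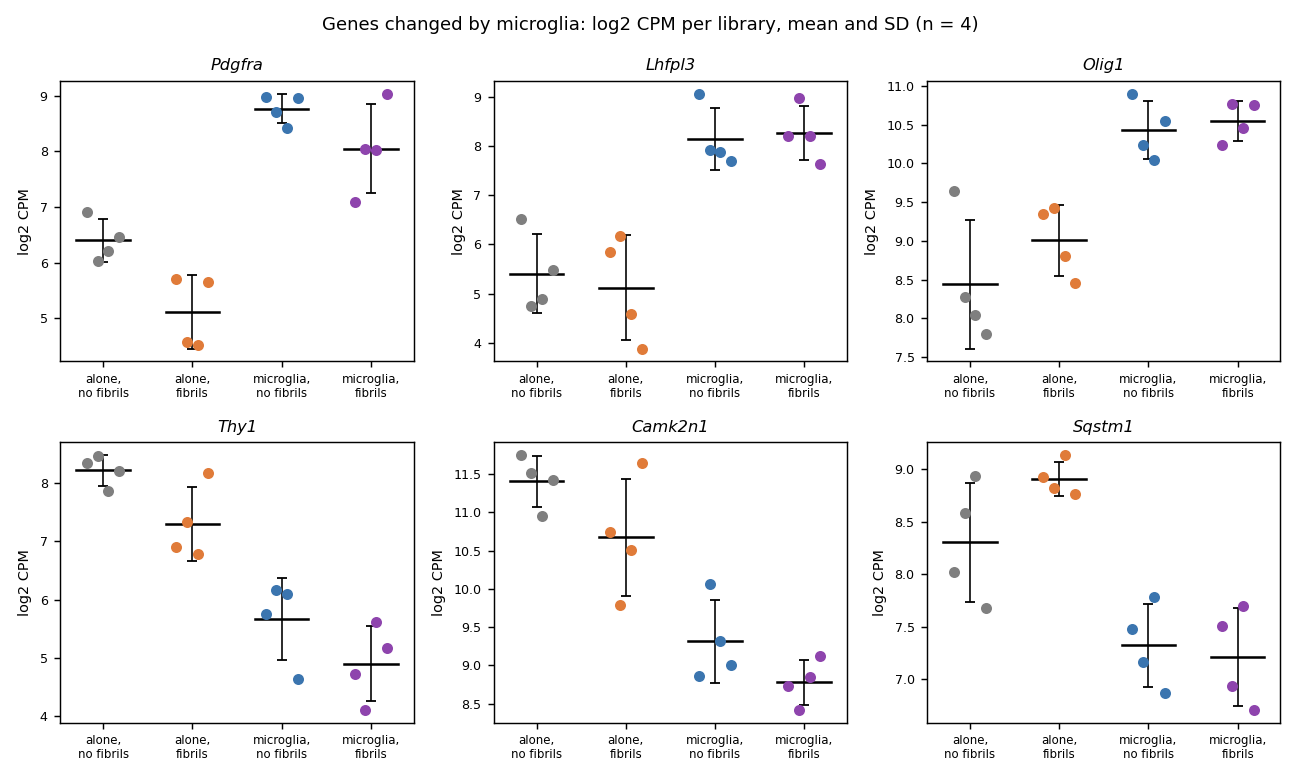
Log2 CPM of 6 genes in each library, by group, with the mean and SD (n = 4). Pdgfra and Lhfpl3 are higher, and Thy1 and Camk2n1 lower, with microglia in both fibril states; Olig1 passed the test without fibrils and Sqstm1 with fibrils.

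A comparison averaged over fibril state was chosen after the separate ones had been seen. In it, 288 of 13139 genes differed between co-culture and neurons alone, 160 up and 128 down (edgeR's quasi-likelihood test). DESeq2 called 1094, limma-voom 662, limma on the authors' normalized values 480 and edgeR 163 against a fold of 1.2. Of the 16 oligodendrocyte-lineage genes 15 were higher and 12 were called. Among the called were Pdgfra (2.67 ± 0.28, SE), Lhfpl3 (2.80 ± 0.37), Cspg4, the NG2 proteoglycan of precursors (2.07 ± 0.32), and Enpp6 (2.14 ± 0.31), with adjusted p from 3.27e-05 to 0.00126. Plxnb3, Sox8, Sh3bp4, Stk32a and Gab1 rose by 2.03 to 2.53 (adjusted p 0.00159 to 0.0403). All 21 cell cycle genes were higher and 5 were called. The called genes included Mki67, a marker of dividing cells (2.15 ± 0.39), Cenpf (1.47 ± 0.32), Hmgb2 (1.36 ± 0.29) and Mcm7, a subunit of the replicative helicase (1.34 ± 0.36). Their adjusted p values were 0.00448 to 0.0471. Lmnb1 rose by 2.17 ± 0.32 (adjusted p = 0.000906).

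Neuronal and synaptic genes were among the falls. Nrgn, a calmodulin-binding postsynaptic protein, was at 5499 ± 1032 and 2905 ± 1581 CPM in untreated and loaded neurons alone and at 616 ± 524 and 341 ± 198 CPM with microglia (SD, n = 4 each; averaged log2 change -3.12 ± 0.48, adjusted p = 0.00387). Camk2a, Grin1 and Dlg4, all of the postsynaptic density, had changes of -2.19 ± 0.53, -1.99 ± 0.38 and -1.72 ± 0.37 (adjusted p = 0.045, 0.00951 and 0.0189). Syn2, Cplx2 and Vamp2 of the synaptic vesicle machinery had changes of -1.78 ± 0.33, -1.82 ± 0.44 and -1.61 ± 0.42 (adjusted p 0.00574 to 0.0475). Thy1, Uchl1, Tubb3 and Eno2, the 4 called neuronal identity genes, changed by -2.43, -1.36, -1.64 and -2.28 (adjusted p 0.000152 to 0.0192). Mef2c, a transcription factor of excitatory neurons, changed by -2.18 ± 0.53 (adjusted p = 0.0456), and Kif5a, a neuronal kinesin, by -1.67 ± 0.27 (adjusted p = 0.0021). Camta2, Spryd3, Tuba4a, Actr3b, Parp6, Slc25a12 and Tmem38a had changes between -1.53 and -2.35 (adjusted p 0.00116 to 0.0407). Of 23 glycolysis and hypoxia genes 21 were lower and 8 were called, with Gpi1, Pgam1, Aldoa and Pfkm at -1.59, -1.03, -1.21 and -1.02 (adjusted p 0.00253 to 0.0262). Pdhb changed by -1.41 ± 0.23 (adjusted p = 0.00253), and of the oxidative phosphorylation list Atp5g1 and Cox8a by -1.01 and -0.73 (adjusted p = 0.0122 and 0.0476). Srxn1 and Fth1, of the antioxidant list, changed by -1.53 and -1.16 (adjusted p = 0.0137 and 0.0411).

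By camera 15 lists were called in this average. Those down besides the ones above were the antioxidant, astrocyte, activity and integrated stress response lists, and those up were oligodendrocyte lineage, cell cycle, ribosomal proteins, microglial identity and interferon response. With an estimated correlation the oligodendrocyte lineage alone held (adjusted p = 0.00297), and the other 14 had adjusted p values from 0.103 to 0.468. By fry, the oligodendrocyte-lineage, glycolysis and hypoxia, cell cycle and oxidative phosphorylation lists passed (adjusted p 1.8e-05 to 0.00854). So did excitatory-neuron, neuronal identity and postsynaptic genes (fry adjusted p 0.0386 to 0.0466). The rest of the 15 had fry adjusted p values from 0.0623 to 0.264. With library totals the split of genes was 339 up and 83 down, and the interferon call was lost (adjusted p = 0.0541). The count of genes was 159 without replicate 2 of the untreated neurons alone, 175 without replicate 1 of the untreated co-cultures, 158 without replicate 2 of the loaded co-cultures, and 152 without both libraries rich in microglial transcripts.

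In neurons alone, no gene passed edgeR's test for an effect of the fibrils. The genes with the smallest p values, none past the threshold by edgeR, were Snhg9, a host of small nucleolar RNAs (122 ± 53.7 and 540 ± 245 CPM; SD, n = 4 each), Taldo1, an enzyme of the pentose phosphate pathway (266 ± 76.9 and 890 ± 366 CPM), Abtb2 (16.5 ± 6.18 and 64.9 ± 15.3 CPM), Ankrd40 and Col11a1, with an adjusted p of 0.371 to 0.446; DESeq2 called these 5 (adjusted p 0.000164 to 0.0028). As lists, ribosomal protein genes (46 of 55 higher, median log2 change 0.57, camera adjusted p = 2.83e-15), antioxidant genes of the Nrf2 pathway (25 of 27, median 1.03, adjusted p = 4.22e-15) and nuclear oxidative phosphorylation genes (59 of 75, median 0.40, adjusted p = 2.89e-12) rose by camera. Each had an adjusted p of 0.312 with an estimated correlation. Members named after their values were seen, none past edgeR's test, were Rps29 (672 ± 198 and 1619 ± 392 CPM), Ftl1, the ferritin light chain (1282 ± 539 and 3034 ± 1304 CPM), Gstm1 (989 ± 420 and 2799 ± 1537 CPM) and Ndufb4 (37.4 ± 12.6 and 118 ± 30.9 CPM; SD, n = 4 each); DESeq2 called Rps29 and Ndufb4 (adjusted p = 0.0039 and 0.00573). Astrocyte, oligodendrocyte-lineage and microglial activation lists rose with medians of 0.49, 0.76 and 0.75 (camera adjusted p 2.06e-06, 0.0129 and 0.0185). With an estimated correlation their adjusted p values were 0.312, 0.312 and 0.403. The rise of the activation list cannot be assigned to microglia, since microglial identity genes summed to 25.9 and 37.8 CPM in untreated and loaded neurons alone. The activation list summed to 1892 and 3005 CPM there, of which Apoe held 1082 and 1976 CPM. Of the 16 tested oligodendrocyte-lineage genes 12 were higher, but Pdgfra was lower (log2 change -1.22 ± 0.38, SE), not past edgeR's test (adjusted p = 0.627).

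Presynaptic genes (25 of 26 lower, median -0.83), activity genes (24 of 25, median -1.0), neuronal identity genes (20 of 22, median -0.72), excitatory-neuron genes (18 of 19, median -0.77) and postsynaptic genes (20 of 22, median -0.66) fell by camera in loaded neurons alone, with adjusted p from 3.41e-11 to 5.68e-05. The adjusted p with an estimated correlation was 0.312 for these 5 lists. Syn2 (508 ± 173 and 186 ± 145 CPM), Fos (126 ± 50.003 and 33.3 ± 25.6 CPM) and Egr1 (305 ± 96.8 and 77.7 ± 77.4 CPM; SD, n = 4 each), named after their values were seen, did not pass. The edgeR count was 0 of 13139, with 909 genes at an unadjusted p under 0.05 against 657 by chance; DESeq2 called 173, and limma-voom and limma on the authors' normalized values called 0. Without replicate 4 of the loaded neurons the edgeR count was 7, and within this group that library had the highest neuronal identity level (8.78 against 6.43 to 7.86) and the lowest oligodendrocyte-lineage level (5.48 against 5.62 to 6.36).

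In co-culture, no gene passed edgeR's test for an effect of the fibrils either. The smallest p values belonged to Sirt2, a deacetylase abundant in oligodendrocytes (275 ± 49.7 and 653 ± 252 CPM; SD, n = 4 each), Lpin2, Dlc1, Hipk2 and Atp6v0c-ps2, with adjusted p = 1 for each; of these DESeq2 called Atp6v0c-ps2 (adjusted p = 0.0221). Atp6v0c-ps2 is a pseudogene copy of Atp6v0c, so its counts are uncertain. Cell cycle genes (20 of 21 lower, median -0.63, camera adjusted p = 1.31e-05) and glycolysis and hypoxia genes (20 of 23, median -0.58, adjusted p = 0.000746) fell as lists. Oligodendrocyte-lineage genes (15 of 16 higher, median 0.69, adjusted p = 0.000466), chaperones of the endoplasmic reticulum (17 of 19, median 0.41, adjusted p = 0.000746) and ribosomal protein genes (42 of 55, median 0.15, adjusted p = 0.00539) rose. With an estimated correlation the adjusted p values were 0.572, 0.495, 0.47, 0.47 and 0.964, in that order, and the ribosomal call was lost with library totals (adjusted p = 0.0776). Bcas1 (340 ± 152 and 1032 ± 609 CPM), Mki67 (193 ± 21.6 and 92.7 ± 33.7 CPM), Vegfa (214 ± 117 and 92.2 ± 47.0 CPM) and Calr (426 ± 84.0 and 653 ± 108 CPM; SD, n = 4 each), named after their values were seen, did not pass. The edgeR count was 0, with 483 genes at an unadjusted p under 0.05 against 657 by chance; DESeq2 called 130, and limma-voom and limma on the authors' normalized values called 0. Leaving out replicate 1 of the untreated co-cultures raised the count of called lists from 5 to 10.

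The difference between the fibril effects with and without microglia was tested as an interaction. By edgeR 0 of 13139 genes passed, with 529 at an unadjusted p under 0.05 against 657 by chance; DESeq2 called 187, and limma-voom and limma on the authors' normalized values called 0. The smallest p values were those of Atp6v0c-ps2, Ndufb4, Zcchc2, Naa38 and Mpst, none past the threshold by edgeR; DESeq2 called the first 3 (adjusted p 0.00127 to 0.00854). By camera 9 lists differed. The fibril effect was lower with microglia for antioxidant genes (median difference -1.0, adjusted p = 1.78e-08), oxidative phosphorylation (-0.39, adjusted p = 2.15e-07), ribosomal proteins (-0.40, adjusted p = 8.07e-06), astrocyte (-1.01, adjusted p = 2.82e-05), microglial activation (-0.98, adjusted p = 0.00645) and interferon response genes (-0.77, adjusted p = 0.0473). It was higher for activity, neuronal identity and presynaptic genes (0.50, 0.28 and 0.36; adjusted p = 0.00016, 0.00375 and 0.00643). Each of the 9 had an adjusted p of 0.731 with an estimated correlation. The count of lists was 14 without replicate 4 of the loaded neurons alone and 5 without replicate 1 of the untreated co-cultures.

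**Figure D3:**
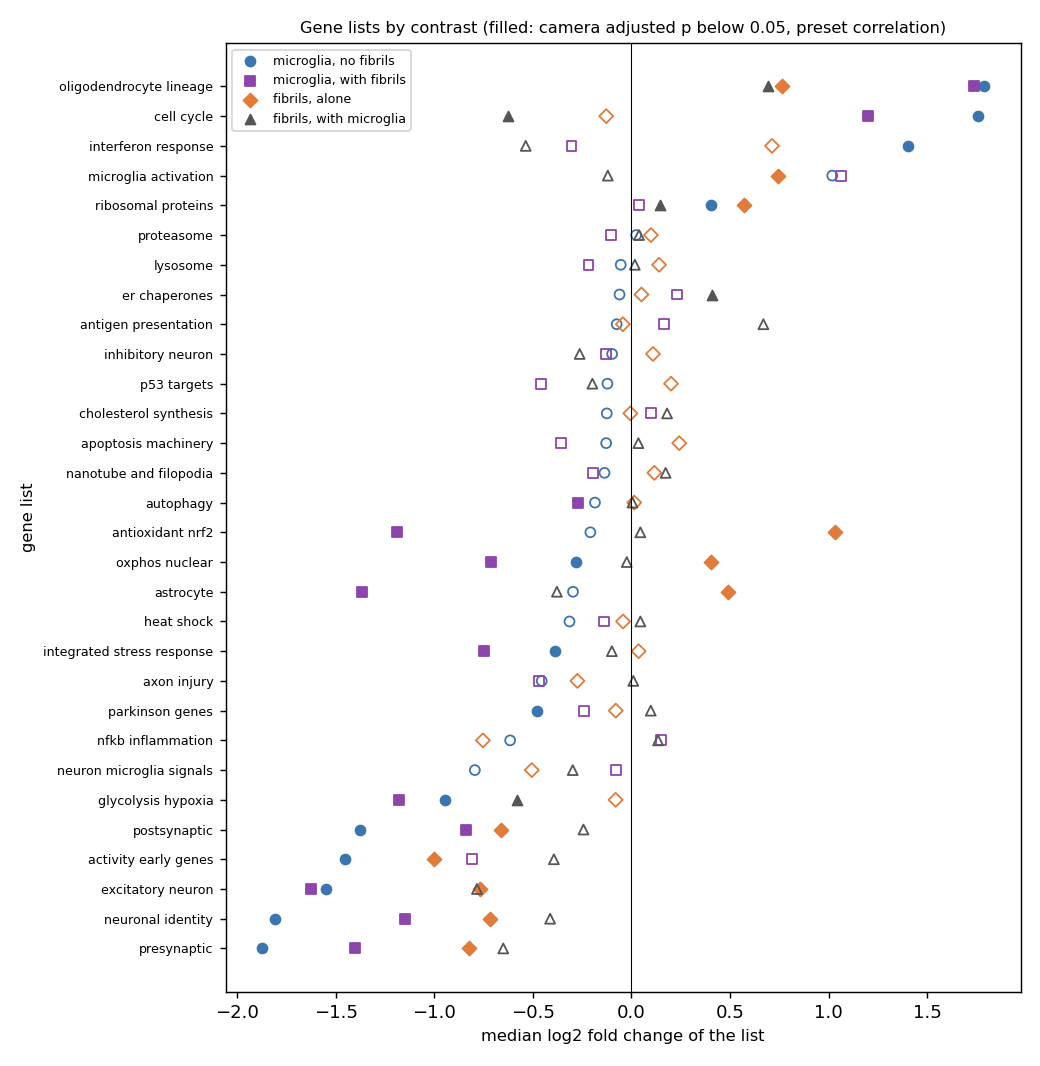
Median log2 fold change (horizontal axis) of 30 fixed gene lists in 4 comparisons, with microglial identity not drawn; filled symbols mark a camera adjusted p below 0.05 at the preset correlation. The oligodendrocyte-lineage list has medians of 1.79 and 1.74 in the microglia comparisons, and the presynaptic list -1.87 and -1.40.

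Because fewer than 20 genes were called for fibrils alone, genes at an unadjusted p under 0.01 (145 higher and 45 lower) were followed into co-culture. With the same loaded libraries on both sides, their median log2 change on adding microglia was -0.65 and 1.59, but unchanged simulated groups gave -1.05 and 2.90, since the shared libraries alone return such values. With the loaded libraries divided between the choice and the test, the mean of the medians over 6 splits was -0.21 (-0.60 to 0.06) for the higher genes and 0.14 (-0.88 to 0.80) for the lower ones, ranges that include 0. The fibril effects with and without microglia, which share no library, had a Pearson correlation of 0.0688 and a Spearman correlation of 0.129 across 13139 genes. Simulated unchanged groups gave -0.00692 ± 0.0162 (SD, 10 simulations), but each gene was drawn on its own there. That SD leaves out variation that genes of real libraries share. Exchanging the labels of 1 untreated and 1 loaded library of the neurons alone gave Pearson values of 0.00416 to 0.0808. The Pearson value was 0.0416 without replicate 1 of the loaded co-cultures and 0.0431 without replicate 2 of the untreated neurons alone. Averaged over culture type, a comparison added later, the edgeR count for fibrils was 0, with 870 genes at an unadjusted p under 0.05; DESeq2 called 257, limma-voom and limma on the authors' normalized values 0. Sirt2, Ehd1, Snhg9, Abtb2 and Tubb4b had the smallest p values, each with an adjusted p of 0.328, and were called by DESeq2 (adjusted p 0.000563 to 0.00217). Camera called 13 lists in this average and 0 with an estimated correlation.

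Positions of the genes most followed here are from the GENCODE annotation of the mouse assembly mm10. Pdgfra lies on chromosome 5 (75152292 to 75198215), Lhfpl3 on chromosome 5 (22746059 to 23275597), Olig1 on chromosome 16 (91269772 to 91271933), Thy1 on chromosome 9 (44043384 to 44048579), Camk2n1 on chromosome 4 (138454314 to 138460123), all on the plus strand. Nrgn on chromosome 9 (37544492 to 37552904) and Sqstm1 on chromosome 11 (50199366 to 50210827) lie on the minus strand. Snhg9 on chromosome 17 (24719531 to 24719965) is annotated as antisense, and without a stated strand setting its counts cannot be parted from those of an overlapping gene.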

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

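All tests of explanations and all counts of other splits in this part were written down after the results had been seen.

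Of 568 sets of 4 libraries looked at, 21 held a library whose gap to the nearest other took a share of the range of the set above Dixon's critical value, against 28.4 expected by chance. Among list levels these were replicate 1 of the untreated co-cultures for microglial identity (gap 0.857; log2 level 5.41 against -1.38 to -0.41), replicate 1 of the untreated neurons alone for astrocyte genes (0.936; 8.42 against 6.55 to 6.67) and replicate 1 of the loaded co-cultures for the proteasome (0.853). The share of Rn45s stood apart in replicate 3 of the untreated co-cultures (0.833; 10.9% against 12.8% to 13.2%). Replicate 4 of the loaded neurons alone stood apart for Taldo1 (0.909), Egr1 (0.849), Aldh1l1 (0.836), Ywhag (0.862) and Camta2 (0.949). Replicate 4 of the untreated neurons alone did so for Cd151 (0.936), Hmgb2 (0.938), Naa38 (0.916) and Tuba4a (0.884), their replicate 1 for Syn2 (0.844) and Uchl1 (0.881), and their replicate 2 for Sirt2 (0.854) and Rpl10 (0.857). In co-culture, Col11a1 (0.854) and Lhfpl3 (0.830) stood apart in untreated replicate 1, Nr4a1 (0.984) in loaded replicate 1 and Vamp2 (0.861) in loaded replicate 2.

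The fibril effect differed between culture types for 9 lists by camera, with adjusted p of 1.78e-08 for antioxidant, 2.15e-07 for oxidative phosphorylation, 8.07e-06 for ribosomal protein, 2.82e-05 for astrocyte, 0.00016 for activity, 0.00375 for neuronal identity, 0.00643 for presynaptic, 0.00645 for microglial activation and 0.0473 for interferon response genes. With an estimated correlation each had an adjusted p of 0.731, and 45 of 100 relabellings of the libraries within culture type called as many lists, the highest other 16, so chance was not excluded.

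Oligodendrocyte-lineage genes were higher in co-culture in both fibril states. RNA carried over in proportion to microglial RNA would leave the libraries with few microglial transcripts at the level of neurons alone, yet the lowest summed level among those 6 libraries was 4287 CPM, above the highest of the neurons alone, 3156 CPM. A lower share of neuronal RNA would raise astrocyte genes alike. Instead, on the log2 scale averaged over fibril state, the oligodendrocyte level rose by 1.75 and the astrocyte level changed by -1.01 (exact permutation p = 0.000408 and 0.0404). The difference was 2.76 (exact permutation p = 0.000408, the smallest value that the 4900 relabellings allow). Oligodendrocyte-lineage cells added with the microglia cannot be told apart from an effect of microglia, because co-culture and whatever came with it are the same libraries; the mean sum was 3.41 times that of neurons alone, led by Olig1 (1419 and 1519 CPM in co-culture), and 14 of the 17 listed genes had a count of at least 10 in every library of neurons alone. The 2 libraries rich in microglial transcripts had the highest sum of their groups. These sums were 8388 CPM against 4287 to 5329 without fibrils, and 10009 CPM against 6198 to 8959 with fibrils. Material that came with the microglia therefore stays open as a source, and no bound on its share of the rise can be set. An effect of microglia on precursors already in the cultures stays open as a hypothesis, which libraries of the microglial preparation alone, not held in this series, would test.

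Excitatory-neuron genes were lower in co-culture by -1.96 averaged over fibril state (exact permutation p = 0.00571). If this came from a lower share of neuronal RNA, inhibitory-neuron genes would fall alike, and the inhibitory level changed less, by a difference of 1.56 (exact permutation p = 0.00612). By that test alone a lower share would have been ruled out, but the list holds Erbb4 and Npy, which other cells can express, so Gad1 and Gad2, the enzymes of GABA synthesis, were added as a condition after this outcome had been seen. These 2 genes changed by -1.75 (exact permutation p = 0.0208), a difference from the excitatory level of 0.21 (exact permutation p = 0.719). A lower share of neuronal RNA and a change within neurons therefore cannot be told apart.

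For fibrils in neurons alone, DESeq2 called 173 genes and edgeR 0. Of the 173, 74.6% had a count of 0 in at least 1 of the 8 libraries, against 39.1% of all tested genes, and 112 had a whole group at 0. Of the 35 splits of the 8 libraries, 8 gave DESeq2 as many genes, the highest other 632, so chance was not excluded. Libraries with a count of 0 may account for many of these calls, but 44 of the 173 had no such library, and no biological explanation was tested.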

How the results depend on the processing

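Averaged contrasts, leaving out Rn45s and leaving out the 2 libraries rich in microglial transcripts were chosen after the results had been seen, and the cause of each change below was not tested unless named. For fibrils alone, microglia without fibrils, microglia with fibrils, fibrils in co-culture, the interaction, averaged microglia and averaged fibrils, DESeq2 called 173, 295, 492, 130, 187, 1094 and 257 genes, against 0, 16, 15, 0, 0, 288 and 0 by edgeR. For the same 2 microglia contrasts and their average, limma-voom called 92, 40 and 662, an adjusted p under 0.01 gave 0, 1 and 60, and a fold of 1.2 gave 5, 9 and 163. Library totals gave 50 and 31, no filter 26 and 26, and the groups of the contrast alone, with fewer libraries, 1 and 0. On the authors' normalized values limma called 35 without fibrils and 480 in the average. Leaving out microglial and 4-fold co-culture genes, or both libraries rich in microglial transcripts, gave 0 without fibrils, and the latter 152 in the average; the left-out genes held 7 of the 16 called, picked by their own rise. With the replicate block the counts were 38 without fibrils and 42 with fibrils, and 4 calls of named genes in the average were not made. Same-numbered libraries did not deviate together in every pair (correlation -0.111 to 0.217, above 0.1 in 4 of 24 pairs). Yet 22 of 48 best matches fell on the own number against 12 by chance (mean correlation 0.0397, and -0.0131 between other numbers). A source shared by same-numbered libraries is therefore not excluded, and the main tests and the other splits did not use the numbers.

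Called lists, in the order above, were 11, 14, 13, 5, 9, 15 and 13 by camera, 0, 1, 1, 0, 0, 1 and 0 with an estimated correlation, and 0, 8, 4, 0, 0, 10 and 0 by fry. The agreement of the fibril effects was 0.0945 and the correlation of the microglia effects 0.295 with a stricter filter. With all 4 loaded libraries in both contrasts, the genes followed into co-culture had medians of -0.65 and 1.59, as shared libraries give.

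Leaving out each library in turn gave 0 to 7 genes for fibrils alone (7 without loaded replicate 4), 0 to 39 for microglia without fibrils, 1 to 26 with fibrils, 0 for fibrils in co-culture and for the interaction, 158 to 333 for averaged microglia and 0 to 1 for averaged fibrils (1 without loaded replicate 4 of the neurons alone). Called lists ranged over 9 to 12, 12 to 17, 6 to 15 (6 without loaded replicate 4 of the neurons alone), 4 to 10, 5 to 14, 13 to 16 and 9 to 17. The microglial marker level difference was 0.50 to 2.77 without fibrils, 0.65 to 3.13 with fibrils, and -0.60 to 2.41 for loaded against untreated co-cultures, where leaving out loaded replicate 1 turned its sign. The agreement of the fibril effects was 0.0416 (without loaded co-culture replicate 1; 0.0431 without untreated replicate 2 of the neurons alone) to 0.101 and the correlation of the microglia effects 0.181 to 0.261. Among named genes, no direction changed. Calls of named genes were lost in 52 cases at an adjusted p under 0.01, 35 without both libraries rich in microglial transcripts, 30 with the groups of the contrast alone, 27 against a fold of 1.2, and 292 over all genes and libraries when each library was left out in turn. Leaving out genes of the mitochondrial genome was not run, since the table held 0 of them.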

Other observations

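The averages, all counts of other splits and the test of exchanged labels in this part were chosen after the results had been seen.

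Several fixed lists had no camera call in any of the 5 contrasts or in the averages. Genes of nanotubes and filopodia, the structures in the title of the series, had median log2 changes on co-culture of -0.12 over 27 genes averaged over fibril state (camera adjusted p = 0.525), with 0 members called. Compared by fibrils, their mean log2 level was 6.77 ± 0.16 and 7.08 ± 0.14 in untreated and loaded neurons alone and 6.66 ± 0.08 and 6.84 ± 0.08 in co-culture (SD, n = 4 each), with 15 and 19 of the 27 genes higher; the camera adjusted p was 0.249 and 0.18, and 0.051 averaged over culture type, none past the threshold. Lysosome genes (median -0.11, adjusted p = 0.731), proteasome genes (-0.03, adjusted p = 0.844), heat shock genes (-0.18, adjusted p = 0.141), p53 targets (-0.14, adjusted p = 0.845), the apoptosis machinery (0.02, adjusted p = 0.731), cholesterol synthesis (0.02, adjusted p = 0.325), inflammatory NF-kB targets (-0.42, adjusted p = 0.999), antigen presentation (-0.20, adjusted p = 0.999), axon injury (-0.57, adjusted p = 0.644), neuron to microglia signals (-0.41, adjusted p = 0.155) and inhibitory-neuron genes (-0.05, adjusted p = 0.731) did not pass in that average either. The median and the test differed in sign for the proteasome (test up) and for apoptosis and cholesterol synthesis (test down). By fry the neuron to microglia signals did pass in that average (adjusted p = 0.011), with 10 of 13 genes lower. They also passed by fry without fibrils (adjusted p = 0.0475) but not with fibrils (adjusted p = 0.0789). With an estimated correlation their adjusted p in the average was 0.277. Single members called by edgeR in that average, chosen after their values were seen, were Tgfb2 (-1.73 ± 0.43, SE; adjusted p = 0.0335) and Il34 (adjusted p = 0.035) among the signals, Ecel1 (adjusted p = 0.039) of axon injury, Atp6v1a (-0.91 ± 0.18, SE; adjusted p = 0.0105) of the lysosome and Cdkn1a (-1.04 ± 0.26, SE; adjusted p = 0.0357) of the p53 targets, all lower in co-culture. A p that misses the threshold does not show that these genes were unchanged.

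Other splits of the libraries into groups of the same sizes tested whether chance gave as many genes. For microglia without fibrils 1 of 35 splits, the real one, gave as many as the 16 genes, with 0 as the highest other, and for microglia with fibrils 1 of 35 gave as many as 15, with 2 as the highest other. For the averaged microglia effect 1 of 100 relabellings within fibril state gave as many as 288, with 1 as the highest other. The real grouping gave the most genes in these 3 comparisons. For the 2 separate contrasts 1 of 35 is the lowest share possible, and no adjustment was made for the number of comparisons. Splits of the neurons alone and of the co-cultures reached 115 and 16 genes, so a structure of the libraries can give counts like those of the separate contrasts. For a count of 0 genes this comparison decides nothing, since every split reaches it: fibrils alone (35 of 35 splits, highest other 115), fibrils in co-culture (35 of 35, highest other 16), the interaction (100 of 100, highest other 187) and averaged fibrils (100 of 100, highest other 126). At an unadjusted p under 0.05 as many genes were found in 5 of 35 splits for fibrils alone (real 909, highest other 1766), 29 of 35 for fibrils in co-culture (483, 1018), 52 of 100 for the interaction (529, 1930) and 8 of 100 for averaged fibrils (870, 1659), so chance was not excluded for these 4 counts.

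The split with 115 genes set replicates 2, 3 and 4 of the untreated and replicate 4 of the loaded neurons against the rest, which points to a structure of the libraries. It is the given grouping with the labels of untreated replicate 1 and loaded replicate 4 exchanged. With this exchange, the most extreme of 35 splits, edgeR called 209 genes for microglia without fibrils and 64 with fibrils, against 16 and 15, as a smaller spread within the groups would give whatever its origin. The libraries in co-culture had no part in that choice. The correlation of the fibril effects alone and in co-culture was 0.0571 with the exchange and 0.0688 with the given labels, a difference smaller than the SD of simulated unchanged groups (0.0162), and the other 15 exchanges gave 0.00416 to 0.0808. The correlation of the 2 microglia effects fell from 0.264 to 0.168 with the exchange, against 0.224 to 0.289 in the other 15, which speaks for the given labels if microglia act alike in both fibril states. A split chosen for parting the neurons alone most widely also lowers this correlation, since each microglia effect is taken against one side of it, so the fall does not exclude an exchange. An exchange of labels and another structure of these 2 libraries cannot be told apart, because the fibril effect in co-culture, with 0 genes called, gives no firm direction to compare with.

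Counts of lists called at the preset correlation were matched more often. As many lists were called in 12 of 35 splits for fibrils alone (real 11, highest other 17), 8 of 35 for microglia without fibrils (14, 17), 5 of 35 with fibrils (13, 16), 23 of 35 for fibrils in co-culture (5, 14), 6 of 100 for averaged microglia (15, 16), 45 of 100 for the interaction (9, 16) and 15 of 100 for averaged fibrils (13, 20). Chance was not excluded for any of these 7 counts of lists, the microglia comparisons included.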
